A study of Mus musculus with 9 samples.

How the data were processed

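RNA levels were measured on 9 one-colour Agilent arrays (design 028005, probes placed on mm9) in mouse LSK cells, the bone marrow fraction that lacks lineage markers, carries Sca1 and cKit, and holds blood stem cells and early progenitors. Per the labels, all cells came from female mice with a tamoxifen-activated Cre at the Rosa26 locus and were kept for 72 h at 50000 cells per well with 250 nM 4OH-tamoxifen, IL-3 and IL-6 at 10 ng/mL each, SCF at 50 ng/mL and 10% serum. The sample titles give 3 groups of 3 repeats, namely control cells, cells with floxed Drosha and cells with floxed Dicer1. The labels do not say that the repeats came from separate animals, so each p-value measures only the spread between these samples, and the number of arrays limits the precision.

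The deposited scanner files hold intensity values in Cy3, which per the file headers were made with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09. The processed signal in them is background-subtracted and spatially detrended, with small values replaced by surrogates, and is not normalised between arrays. The authors' series values are on a log2 scale and share nearly the same quantiles in all 9 columns, as after quantile normalisation, with no centring of probes. The medians of the authors' columns were 6.37, 6.37 and 6.38 for control replicates 1 to 3, 6.37, 6.36 and 6.37 for the Drosha-deleted replicates, and 6.37 in each Dicer-deleted replicate. The submitters' notes name limma without a version, and their background step, any weighting of arrays and the array behind each column are not given in the sources used here.

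Each array had 62976 spots, of which 3671 were control spots and were left out, as were spots that the scanner software marked as non-uniform or as population outliers. The spots other than controls belonged to 55681 probes. A probe was kept when it lay well above background on every array of at least 1 group, which left 31490 probes. Probes were named through their accession for 26413, by a current symbol for 3859, by a synonym for 735 and by a lincRNA region for 16194, while 8480 kept another name from the file, which gave 36315 genes or regions. Symbols, and which genes neighbour each other, came from a table of the GRCm38.p6 assembly, whose coordinates were not used; all positions printed are probe or region positions on mm9. A gene was represented by its kept probe with the highest mean, and needed values on at least 2 arrays per group, so that 23026 genes or regions were tested in the scanner values and 23027 in the authors' values.

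The scanner signal was taken as log2 and the 75th percentile of each array was subtracted. Groups were compared with limma 3.58.1 in R 4.3.3 with data.table version 1.17.8, with a mean per group fitted over all 9 arrays, moderated tests, and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. A moderated F test asked which genes differed among the 3 groups. The same tests were run on the authors' values. Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists of a comparison, and again with a correlation estimated for each list; both p-values are given, the second as "with an estimated correlation". Differences of lists are medians over the members less the median over all genes. All tests of differences were two-sided.

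The groups, comparisons, filter, lists, tests, alternatives and the rule for naming genes were set before the data were examined. Per comparison, the rule names the 12 largest positive and the 12 largest negative differences past the threshold, without accession-like names, then Drosha, Dicer1 and the measured mRNAs reported as cleaved by Drosha, and up to 4 members of each list with the smallest adjusted p. Not every gene that the rule names is reported here. Applying the same rule to the authors' values was decided after the data were seen, and accession-like genes, noncoding regions and counts of features near microRNA genes were likewise chosen after their values were seen. The list of mRNAs reported as cleaved by Drosha holds Myl9 and Todr1, which are known from published work that was probably done on these same samples, so its direction is not independent evidence. Regions near microRNA genes are array lincRNA regions whose neighbouring named protein-coding genes on mm9 are the same pair that flank a microRNA gene in the gene order of the GRCm38.p6 table. Where a group was not well above background, a fold is given as a lower bound against the background limit.

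Recovery was tested on simulated data with the spread of these arrays and 100 changed genes per size. With the scanner values, the share of 2-unit log2 changes recovered was 25% for Drosha-deleted against control, 41% for Dicer-deleted against control, and 20% and 32% for the comparison of the deletions when the change was placed in the Drosha-deleted or the Dicer-deleted group. For 1-unit changes these shares were 1%, 2%, 0% and 0%. With the authors' values they were 94%, 97%, 94% and 91% for 2 units and 70%, 59%, 66% and 53% for 1 unit. Unchanged genes called in the same fits, in the same order, numbered 4, 8, 0 and 0 with the scanner values. With the authors' values they numbered 14, 14, 2 and 2. The simulation drew noise independently for each gene, so the shift of control replicate 2 over all genes was not kept as a shift.

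Alternatives tried were normexp background correction with an offset of 50, quantile normalisation, the authors' values, no filter and a stricter filter, replicate number as a block, slide as a block, leaving out each array, fitting only the compared groups, a trended robust prior, array weights, the mean of a gene's probes, a minimum 1.5-fold difference and the estimated correlation. A further 3 were added after the data were seen, namely the authors' values without control replicate 2, quantile normalisation without control replicate 2, and keeping the marked spots. A planned test of genes with microRNA seed matches was not run, because no transcript sequences were at hand.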

Results

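Gene expression was measured in LSK cells from mouse bone marrow after 72 h in culture, on 9 arrays in 3 groups of 3, namely control cells, Drosha-deleted cells and Dicer-deleted cells. Drosha cleaves primary microRNA transcripts in the nucleus together with Dgcr8, and Dicer, encoded by Dicer1, trims the product in the cytoplasm. Loss of either enzyme stops most microRNA production, so a comparison of each deletion with the controls asks what the loss of microRNAs does, and a comparison of the deletions with each other asks what Drosha does beyond the step it shares with Dicer. Between 54.2% and 62.3% of probes were well above background on 8 of the arrays.

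Control replicate 2 stood apart from the other arrays in its scanner file. Of its spots 18.9% were marked as non-uniform, against at most 0.0472% elsewhere, its median signal was 529 against 31.0 to 53.8, and 93.2% of its probes were well above background. Its highest correlation across probes with another array was 0.785, where each other array reached at least 0.977 with its closest neighbour. The authors' column for this sample correlated at 0.818 with its own scanner file, against 0.993 or more for the other 8, so the column does not match the file held for it. With control replicate 2 in the scanner fit, the median difference of all genes was 0.36 log2 units for Drosha-deleted and 0.37 for Dicer-deleted cells against controls; without it these were −0.01 and 0.01, and in the authors' values with all 9 columns both lay within 0.01 of 0. Differences against controls from the scanner values are to be read against that shift. By the scanner's slide codes control replicate 3 was alone on its slide and the other 8 arrays shared another. Replicate numbers did not pair the samples: the deviations of arrays with the same number correlated at −0.27 to 0.15, and those with different numbers at −0.16 to 0.25.

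**Figure D1:**
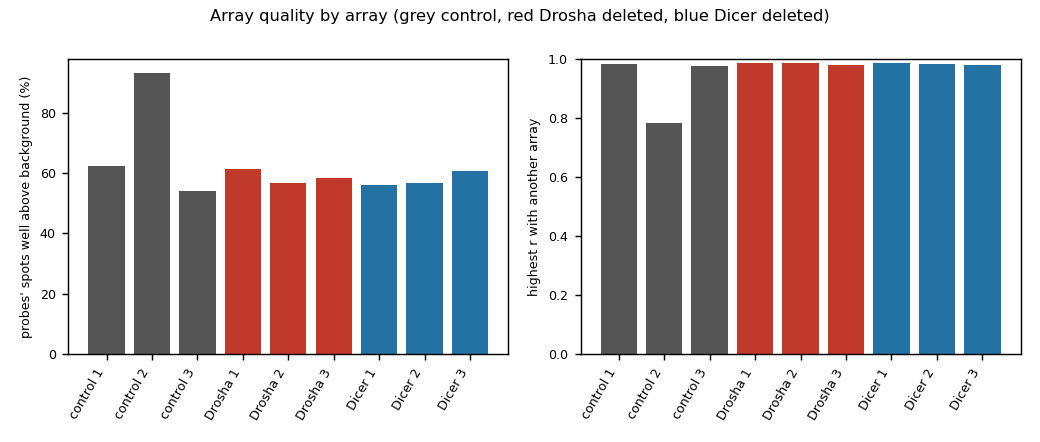
Percent of probes well above background and highest correlation across probes with another array, for each of the 9 arrays (bars). Control replicate 2 lies at 93.2% and 0.785, apart from the other 8 arrays.

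Drosha RNA was lower in Drosha-deleted cells, and Dicer1 RNA had its lowest mean in Dicer-deleted cells. On the scale of log2 signal less the array's 75th percentile, Drosha stood at 2.19 ± 0.91 in controls, −0.37 ± 0.36 in Drosha-deleted and 2.72 ± 0.19 in Dicer-deleted cells (SD, n = 3). The difference from controls was −2.56 (SE 0.45), 5.89-fold lower, which missed the threshold with the scanner values (adjusted p = 0.0919) and passed it when control replicate 1 (−2.33, adjusted p = 0.0345) or control replicate 2 (−3.08, adjusted p = 0.0105) was left out. With the authors' values, Drosha fell by 2.91 against controls (7.52-fold, adjusted p = 0.000152) and by 3.02 against Dicer-deleted cells (8.08-fold, adjusted p = 0.000124). Dicer1 stood at 0.98 ± 0.45 (SD, n = 2) in controls, 1.17 ± 0.43 (SD, n = 3) in Drosha-deleted and −0.29 ± 0.14 (SD, n = 3) in Dicer-deleted cells. Its difference in Dicer-deleted cells from controls was −1.28 (adjusted p = 0.653), and −1.24 in the authors' values (adjusted p = 0.118), so it did not pass limma's test in either source. Both Drosha probes (mm9, chromosome 15, 12864767 to 12864826 and 12864964 to 12865023) and the Dicer1 probe (chromosome 12, 105926064 to 105926123) lie at the 3′ end of their genes. The deleted exons are not given in the sources used here, and a probe outside the deleted part could miss a deletion. The Drosha probes read −0.90 to 0.03 on the Drosha-deleted arrays and 1.14 to 2.93 on the others. Dicer1 read −0.42 to −0.15 on the Dicer-deleted arrays and 0.67 to 1.56 on the others that had a value. These levels go with the group labels.

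**Figure D2:**
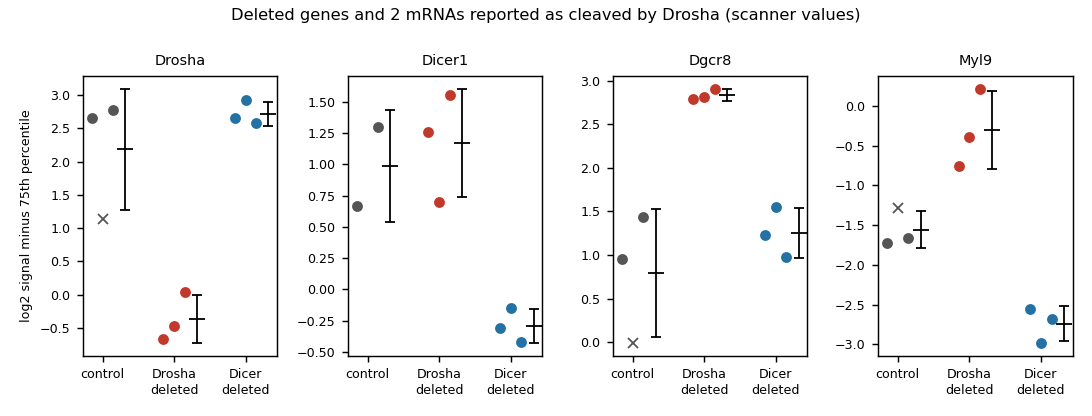
Scanner values of Drosha, Dicer1, Dgcr8 and Myl9 on each array (log2 relative to the array's 75th percentile; points are arrays, crosses control replicate 2, bars mean ± SD). Drosha averages −0.37 in Drosha-deleted cells against 2.19 in controls.

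Beside microRNA genes, 2 noncoding regions were higher and 1 was lower in Drosha-deleted cells than in controls, and a few weakly expressed genes were lower. A region on chromosome 15 (mm9, 68170864 to 68171544), between Zfat and Khdrbs3 like the genes of miR-30b and miR-30d, rose by 3.1 log2 units (adjusted p = 0.0391), and a region on chromosome 6 (mm9, 31007184 to 31007725), between Klf14 and Mkln1 like those of miR-29a and miR-29b-1, rose by 3.07 (adjusted p = 0.0391). The predicted gene LOC100046362 rose from −3.90 ± 0.05 (SD, n = 2) to −1.12 ± 0.29 (SD, n = 3), by 2.78 (adjusted p = 0.0391 in limma). Olfr792, an odorant receptor gene (mm9, chromosome 10, 128978467 to 128978526), fell from −3.37 ± 0.49 in controls to −6.93 ± 0.22 (SD, n = 3), a difference of −3.56 (SE 0.36, adjusted p = 0.00305), at least 2.97-fold lower. LOC640408 (at least 4.38-fold, adjusted p = 0.0119), EG667188 (at least 2.09-fold, adjusted p = 0.0391) and a region on chromosome 12 (mm9, 77550684 to 77551505; at least 5.33-fold, adjusted p = 0.0193), between Ppp1r36 and Plekhg3 like the gene of miR-5135, were also lower. These 3 higher and 4 lower features were all that passed limma's test among 23026, where 2243 had an unadjusted p under 0.05. Of the 3 higher features 2 lay near a microRNA gene, and of the 4 lower ones 1 did. Of the 7, LOC100046362 and the regions on chromosomes 12, 15 and 6 passed in the authors' values too, while Olfr792 did not (−0.66, adjusted p = 0.138).

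The count depended on single arrays. Leaving out control replicate 1 gave 1369 genes, 1312 higher and 57 lower, with the median of all genes at 0.54, and without control replicate 3 there were 13. It was 0 without Drosha-deleted replicate 1 (1006 with an unadjusted p under 0.05 in limma), 1 without Drosha-deleted replicate 2 or 3, and 4, 3 and 3 without Dicer-deleted replicates 1, 2 and 3. Olfr792 lost its call without Drosha-deleted replicate 1 (adjusted p = 0.0540) and with no other array left out. LOC640408 lost its call with control replicate 2 (adjusted p = 0.0967) or any Drosha-deleted array left out (adjusted p = 0.0753 to 0.0932), and the region on chromosome 12 with any Drosha-deleted array left out (adjusted p = 0.0932 to 0.212). LOC100046362 lost its call with control replicate 3 (adjusted p = 0.0749) or any deletion array left out (adjusted p = 0.0713 to 0.260), and EG667188 with control replicate 2 (adjusted p = 0.113) or any deletion array left out (adjusted p = 0.0652 to 0.260). The region on chromosome 6 lost its call in the same cases as EG667188 (adjusted p = 0.0967 without control replicate 2, 0.0640 to 0.264 without a deletion array). That on chromosome 15 lost its call without control replicate 2 (adjusted p = 0.0993), control replicate 3 (adjusted p = 0.0692) or any deletion array but Dicer-deleted replicate 1 (adjusted p = 0.0640 to 0.260).

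In the authors' values, 28 features were higher and 11 lower in Drosha-deleted cells than in controls, with 6197 at an unadjusted p under 0.05, and transcripts that carry microRNAs stood among the higher. Aopep encodes an aminopeptidase, and its gene holds miR-23b, miR-27b and miR-24-1. It rose from 10.29 ± 0.01 in controls to 12.70 ± 0.13 (SD, n = 3) in Drosha-deleted cells, 5.34-fold (adjusted p = 0.000110), against 10.50 ± 0.08 in Dicer-deleted cells. Mir22hg, the noncoding host of miR-22, rose 3.00-fold from 7.55 ± 0.19 to 9.14 ± 0.37 (SD, n = 3; adjusted p = 0.0406). Dgcr8, which encodes Drosha's partner and whose mRNA Drosha is reported to cleave, rose 3.15-fold from 10.67 ± 0.21 to 12.32 ± 0.12 (SD, n = 3; adjusted p = 0.0109). Cfl2, an actin-severing cofilin, rose by 1.69 log2 units (adjusted p = 0.0138), and Asph, an aspartyl hydroxylase, by 1.76 (adjusted p = 0.0169). The scanner values had Aopep higher by 3.01 (adjusted p = 0.0543, and 0.0310, 0.010 and 0.0491 without control replicates 1, 2 and 3), Dgcr8 by 2.04 (adjusted p = 0.172) and Mir22hg by 1.86 (adjusted p = 0.158), short of the threshold. Higher regions included those between Kcnrg and Dleu7 on chromosome 14 (mm9, 62254361 to 62301162; 2.23, adjusted p = 0.00208), where miR-15a and miR-16-1 lie, and between Jak1 and Ak4 on chromosome 4 (mm9, 101010948 to 101032148; 2.46, adjusted p = 0.00480), where miR-101a lies. Of the 28 higher features 10 held or lay near a microRNA gene, against 4.21% of features tested, and of the 11 lower ones 1 did. Neighbouring features are not independent, and noncoding regions rose as a class. The 2790 regions with no microRNA gene between their neighbours had a median of 0.26 over all genes, with 4 called higher. For the 372 regions near a microRNA gene the median was 0.35, with 7 called higher.

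Among those lower in Drosha-deleted cells in the authors' values were Lrmda, a melanocyte differentiation gene (−1.98, 3.95-fold, adjusted p = 0.00208), Pdpn, the membrane glycoprotein podoplanin (−1.75, adjusted p = 0.0243), the lectin receptor gene Clec4d (−1.21, adjusted p = 0.0289) and Cd14, a monocyte coreceptor for endotoxin (−1.26, adjusted p = 0.0300). In the scanner values Cd14 differed by −0.33 (adjusted p = 0.799). Without the column of control replicate 2 the authors' values gave 6 features, with Aopep (2.41, adjusted p = 0.00179), Drosha, Lrmda (−2.02, adjusted p = 0.0145), LOC100046362 and the regions on chromosomes 14 and 4 still past the threshold. Those that lost it included Dgcr8 (1.70, adjusted p = 0.0591), Cfl2, Asph and Pdpn (each adjusted p = 0.0834), and Mir22hg and Cd14 (each adjusted p = 0.147). The other columns were not left out one at a time.

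As lists, primary microRNA host transcripts and mRNAs reported as cleaved by Drosha were higher in Drosha-deleted cells than in controls. The 6 of 19 host transcripts measured had a median difference of 1.21 log2 units over all genes (adjusted p = 2.42e-06; 3.51e-05 with an estimated correlation), and 4 of them were higher when adjusted over the list alone, while 0 passed over all genes in limma. The median was smaller, and past the threshold, in the authors' values (0.68), with normexp background (0.57) and with no filter (0.47). The cleaved mRNAs measured were Dgcr8, Myl9 and Nfib, with a median of 0.89 (adjusted p = 0.00126; 0.00207 with an estimated correlation), 2 of them higher over the list alone, which is not independent evidence since Myl9 was picked in published work probably done on these samples. Todr1 had no probe matched and Neurog2 did not pass the filter. Monocyte and macrophage genes had a median of −0.50 (adjusted p = 1.44e-06; 0.932 with an estimated correlation), and their named members were Msr1 (−1.67), a scavenger receptor, and Cx3cr1 (−1.99), a chemokine receptor. Interferon-stimulated genes had a median of −0.35 (adjusted p = 2.22e-06; 0.932 with an estimated correlation), among them the antiviral gene Ifit1 (−1.16), and cell cycle genes one of 0.24 (adjusted p = 0.00400; 0.932 with an estimated correlation), among them the cyclin gene Ccne2 (2.29). With the scanner values none of these 3 lists held with an estimated correlation or had a member past the threshold over the list alone. In the authors' values the monocyte and macrophage genes (−0.48, adjusted p = 0.000144; 0.476 with an estimated correlation) had 5 members lower over the list alone and 1 over all genes. The megakaryocyte genes passed there too (−0.23, adjusted p = 0.00449; 0.640 with an estimated correlation), with 5 lower over the list alone. Without control replicate 1 the host list (adjusted p = 0.0566), the cleaved mRNAs (0.63, adjusted p = 0.244), the interferon-stimulated genes (−0.20) and the cell cycle genes (each adjusted p = 0.0612) lost their calls. Without control replicate 2 the cell cycle genes lost theirs (0.11, adjusted p = 0.359), the cleaved mRNAs had a median of 1.40, and the monocyte and macrophage median became −0.70. Without Drosha-deleted replicate 3 there were 8 lists past the threshold in place of 5, and without control replicate 1 there was 1.

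Dicer-deleted cells differed from controls in the same direction as Drosha-deleted cells in the few genes that passed. LOC100046362 (mm9, chromosome 4, 27794264 to 27794323) rose by 2.94 to −0.96 ± 0.11 (SD, n = 3; adjusted p = 0.0349 in limma). Olfr792 fell by 3.37 to −6.74 ± 0.01 (SD, n = 3; adjusted p = 0.00592 in limma), at least 3.15-fold, and LOC640408 fell by 4.00 (adjusted p = 0.0214), at least 4.65-fold. These were all 3 features past the threshold, with 1738 at an unadjusted p under 0.05. Both lower genes and the higher one were also past it in Drosha-deleted cells, but the same controls served both comparisons. In 100 simulated draws with no difference between groups, the spread of each group kept, 20.4 lower and 19.1 higher features were shared on average. These draws treated the shift of control replicate 2 over all genes as independent noise in each gene. They do not measure what shared controls alone give, and the sharing is not taken as a sign of a common effect. Independent calls would share 0.000347 lower and 0.000130 higher. Those draws also called 27.1 lower and 25.7 higher features on average for Drosha-deleted cells, and 27.7 and 26.8 for Dicer-deleted cells, more than the real arrays did. The count was 772 without control replicate 1, 744 higher and 28 lower, with the median of all genes at 0.56, and 0 whichever Dicer-deleted replicate was left out, where limma gave 1011, 711 and 989 genes at an unadjusted p under 0.05 without replicates 1, 2 and 3. Olfr792 then had an adjusted p of 0.0674, 0.0750 and 0.0693. LOC100046362 (adjusted p = 0.187 to 0.376) and LOC640408 (adjusted p = 0.0931 to 0.123) missed the threshold there too. LOC100046362 also lost its call with control replicate 3 (adjusted p = 0.143) or any Drosha-deleted array left out (adjusted p = 0.0982 to 0.104), and LOC640408 without control replicate 2 (adjusted p = 0.221), control replicate 3 (adjusted p = 0.120) or Drosha-deleted replicate 3 (adjusted p = 0.0740).

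Lrmda (−1.82, adjusted p = 0.0116), Pdpn (−1.94, adjusted p = 0.0496) and H2-Eb2, a class II histocompatibility gene (−1.11, adjusted p = 0.0496), were lower in Dicer-deleted cells than in controls with the authors' values, and LOC100046362 was higher (1.96, adjusted p = 0.0116). These were the 4 features past the threshold, with 5040 at an unadjusted p under 0.05. Lrmda and Pdpn were thus lower in both deletions. Simulated draws with no difference between groups gave 2.07 shared lower features on average. Those draws treated the noise as independent between genes, so they do not measure what shared controls alone give. The sharing is not taken as a sign of a common effect. Without the column of control replicate 2 LOC100046362 alone was left (2.1, adjusted p = 0.0291), with Lrmda at an adjusted p of 0.0557, Pdpn at 0.154 and H2-Eb2 at 0.256. Aopep, Dgcr8 and Mir22hg did not pass here.

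Lists of genes of several mature blood lineages had lower medians in Dicer-deleted cells than in controls, much of it through a single array for the monocyte, dendritic and eosinophil genes. Dendritic cell genes had a median of −0.62 (adjusted p = 3.16e-07; 0.428 with an estimated correlation), among them the chemokine receptor gene Ccr7 (−1.49). Megakaryocyte genes had one of −0.51 (adjusted p = 5.40e-06; 0.552 with an estimated correlation), among them the platelet collagen receptor gene Gp6 (−1.46). The medians were −0.36 for monocyte and macrophage genes (adjusted p = 7.21e-06; 0.556 with an estimated correlation), −0.51 for eosinophil genes (adjusted p = 0.00486; 0.552 with an estimated correlation), −0.41 for B lymphoid genes (adjusted p = 0.0242; 0.126 with an estimated correlation) and −0.45 for T and NK lymphoid genes (adjusted p = 0.0125; 0.126 with an estimated correlation). Interferon-stimulated genes had a median of −0.45 (adjusted p = 1.09e-07; 0.552 with an estimated correlation), among them the antiviral genes Ifit1 (−1.49) and Mx1 (−1.25), and cell cycle genes one of 0.15 (adjusted p = 0.0195; 0.931 with an estimated correlation). None of the 8 held with an estimated correlation, and in limma 0 members of any of them passed over the list alone. In the authors' values the megakaryocyte genes had a median of −0.68 (adjusted p = 4.56e-12; 0.267 with an estimated correlation), with 18 of 25 lower when adjusted over the list alone. The eosinophil (adjusted p = 0.589), B lymphoid (adjusted p = 0.701), T and NK lymphoid (adjusted p = 0.641) and cell cycle genes (adjusted p = 0.175) did not pass in the authors' values. Contractile and actomyosin genes passed there alone (−0.24, adjusted p = 0.00957; 0.415 with an estimated correlation), with 3 lower and 1 higher over the list alone.

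Of these 8 list calls, 5 rested on single arrays. Dicer-deleted replicate 2 stood apart: its members' mean deviation was −0.92 for monocyte, −0.75 for dendritic and −1.79 for eosinophil genes, against 0.16, −0.11 and −0.24 in replicate 1 and 0.54, 0.16 and 0.46 in replicate 3. Without it only 3 lists passed. The monocyte and macrophage (−0.09, adjusted p = 0.181) and eosinophil genes (−0.04, adjusted p = 0.700) were among those lost, and the dendritic cell median was −0.25 (adjusted p = 0.00581). Without Dicer-deleted replicate 1 the monocyte and eosinophil medians were −0.66 and −0.83, and without replicate 3 the eosinophil median was −0.90. Without control replicate 2 the eosinophil genes lost their call (adjusted p = 0.534) and 6 lists passed, with the megakaryocyte median at −0.64. Without control replicate 1 there were 5. The B lymphoid genes lost their call without control replicate 1 (adjusted p = 0.0653), control replicate 2 (median 0.254, adjusted p = 0.891), Dicer-deleted replicate 1 (adjusted p = 0.0623) or Dicer-deleted replicate 2 (median −0.24, adjusted p = 0.201). The T and NK lymphoid genes lost it without control replicate 1 (adjusted p = 0.142), control replicate 2 (median −0.27, adjusted p = 0.492) or Dicer-deleted replicate 2 (adjusted p = 0.0611). The cell cycle genes lost it without the same arrays (medians 0.23, 0.02 and 0.15; adjusted p = 0.0780, 0.969 and 0.0668). Without control replicate 3 the B lymphoid median was −0.73 and the cell cycle median 0.27.

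A region beside a microRNA gene was higher in Drosha-deleted than in Dicer-deleted cells, and the cell adhesion gene Cadm1 was lower. This region, between Jak1 and Ak4 on chromosome 4 where miR-101a lies, was higher by 2.95 log2 units (SE 0.37, adjusted p = 0.0317), and by 2.88 in the authors' values (adjusted p = 0.00157). Cadm1 (mm9, chromosome 9, 47658414 to 47658473) stood at −6.21 ± 0.44 in Drosha-deleted and −3.02 ± 0.21 in Dicer-deleted cells (SD, n = 3), a difference of −3.19 (SE 0.39, adjusted p = 0.0317), at least 3.81-fold, and at −5.48 ± 0.59 (SD, n = 2) in controls. Cadm1 differed by −1.19 in the authors' values (adjusted p = 0.114). With the scanner values these were the 2 features past limma's threshold, and 351 had an unadjusted p under 0.05. The count was 5 without control replicate 2. It was 0 when control replicate 1 or any deletion array was left out, where 236 to 394 genes had an unadjusted p under 0.05 in limma; without control replicate 1 the adjusted p was 0.104 for the region and 0.134 for Cadm1, and with a deletion array left out both lay between 0.102 and 0.228.

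The authors' values gave 12 higher features and 1 lower, Drosha itself, between the deletions, with 1302 at an unadjusted p under 0.05. Aopep was 4.60-fold higher in Drosha-deleted than in Dicer-deleted cells (adjusted p = 0.000124), Mir22hg 3.79-fold (adjusted p = 0.0272), Dgcr8 higher by 1.60 log2 units (adjusted p = 0.0166), Cfl2 by 1.69 (adjusted p = 0.0170) and the urea transporter gene Slc14a1 by 1.14 (adjusted p = 0.0499). Regions near miR-15a and miR-16-1 on chromosome 14 (2.45, adjusted p = 0.00127), miR-29a and miR-29b-1 on chromosome 6 (2.71, adjusted p = 0.0145), and miR-30b and miR-30d on chromosome 15 (2.15, adjusted p = 0.0170) were higher as well. Regions near miR-99a on chromosome 16 (mm9, 77670599 to 77691642; 2.11, adjusted p = 0.0391) and near miR-503 and miR-322 on chromosome X (mm9, 50407969 to 50410370; 1.38, adjusted p = 0.0391) were too. Of the 12 higher features, 9 held or lay near a microRNA gene. Without the column of control replicate 2 there were 11 features past the threshold, Aopep, Dgcr8, Cfl2, Drosha and the regions on chromosomes 4, 6, 14 and 15 among them, while Mir22hg (adjusted p = 0.0533), Slc14a1 (adjusted p = 0.0848) and the regions on chromosomes 16 and X were not.

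**Figure D3:**
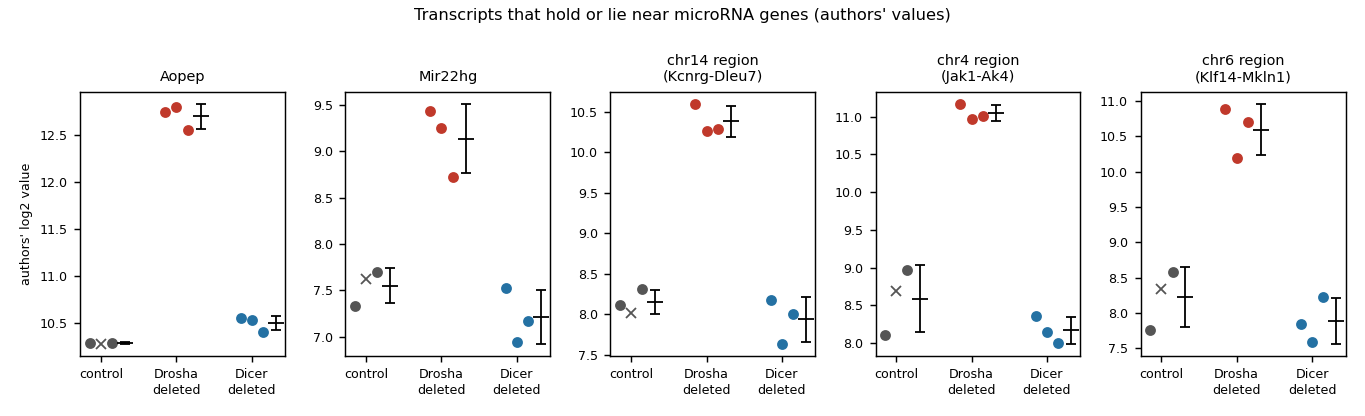
Authors' log2 values of Aopep, Mir22hg and the regions between Kcnrg and Dleu7, Jak1 and Ak4, and Klf14 and Mkln1 on each array (points are arrays, crosses control replicate 2, bars mean ± SD). Aopep lies at 12.70 in Drosha-deleted cells, against 10.29 in controls and 10.50 in Dicer-deleted cells.

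Myl9, a myosin regulatory light chain whose mRNA is reported to be cleaved by Drosha, had its highest mean in Drosha-deleted and its lowest in Dicer-deleted cells, without passing the threshold over all genes. It stood at −1.56 ± 0.23 in controls, −0.31 ± 0.49 in Drosha-deleted and −2.74 ± 0.22 in Dicer-deleted cells (SD, n = 3). The difference between the deletions was 2.43 (SE 0.37, adjusted p = 0.0698), 5.39-fold, and 2.09 in the authors' values (adjusted p = 0.0624), 4.25-fold. Without the column of control replicate 2 the authors' difference of 2.09 passed (adjusted p = 0.0387). Against controls Myl9 differed by 1.25 in Drosha-deleted (adjusted p = 0.494) and by −1.18 in Dicer-deleted cells (adjusted p = 0.653).

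As lists, 9 of 21 were higher in Drosha-deleted than in Dicer-deleted cells and none lower with the scanner values. Monocyte and macrophage genes were lower in the authors' values (−0.12, adjusted p = 0.0338; 0.704 with an estimated correlation), with the stricter filter (−0.10, adjusted p = 0.00900) and without Dicer-deleted replicate 2 (−0.36, adjusted p = 3.45e-09), but higher without Dicer-deleted replicate 3 (0.17, adjusted p = 0.0170). Primary microRNA host transcripts had a median difference of 1.5 (adjusted p = 5.78e-22; 1.97e-19 with an estimated correlation; 4 higher over the list alone; 0.85 in the authors' values, 0.74 with normexp background and 0.39 with no filter, each past the threshold), and mRNAs reported as cleaved by Drosha one of 1.60 (adjusted p = 1.71e-16; 6.19e-17 with an estimated correlation; 2 higher over the list alone). Eosinophil genes had a median of 0.25 (adjusted p = 3.51e-11; 0.0260 with an estimated correlation), with 5 members higher when adjusted over the list alone; the ribonuclease gene Ear2 stood at 2.15 ± 0.26 in Drosha-deleted and −0.97 ± 2.07 in Dicer-deleted cells (SD, n = 3). Much of the eosinophil difference came from Dicer-deleted replicate 2, where the members lay on average −1.79 from their mean over all arrays, against −0.24 and 0.46 in Dicer-deleted replicates 1 and 3 and 0.42 to 0.94 in Drosha-deleted cells. The median was 0.07 without that array (adjusted p = 7.24e-05), 0.47 without Drosha-deleted replicate 2 or 3, 0.58 without Dicer-deleted replicate 1 and 0.85 without Dicer-deleted replicate 3. B lymphoid genes had a median of 0.24 (adjusted p = 0.0108; 0.0260 with an estimated correlation), which was lost without Drosha-deleted replicate 3 (0.07, adjusted p = 0.142) or Dicer-deleted replicate 2 (0.10, adjusted p = 0.307). The eosinophil (adjusted p = 0.146 with an estimated correlation) and B lymphoid genes (adjusted p = 0.162 with an estimated correlation) did not hold that way in the authors' values. Only 3 of the cleaved mRNAs were measured. Their direction is not independent evidence, since Myl9 was picked in published work probably done on these samples.

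The remaining 5 lists held only at the preset correlation. They were dendritic cell genes (median 0.24, adjusted p = 3.42e-08; 0.238 with an estimated correlation), with 1 member higher over the list alone, megakaryocyte genes (0.34, adjusted p = 6.97e-07; 0.444 with an estimated correlation), neutrophil granule and maturation genes (0.36, adjusted p = 0.00251; 0.875 with an estimated correlation), T and NK lymphoid genes (0.11, adjusted p = 0.0165; 0.0575 with an estimated correlation) and contractile and actomyosin genes (0.16, adjusted p = 0.0165; 0.875 with an estimated correlation), with 1 member higher over the list alone. The dendritic cell median was 0.08 without Dicer-deleted replicate 2 (adjusted p = 0.0180), 0.38 without replicate 1, 0.42 without replicate 3 and 0.44 without Drosha-deleted replicate 1. The neutrophil genes lost their call without Drosha-deleted replicate 1 (0.16, adjusted p = 0.176) or Drosha-deleted replicate 2 (0.28, adjusted p = 0.172), and turned to −0.06 without Dicer-deleted replicate 2 (adjusted p = 0.427). Without Dicer-deleted replicates 1 and 3 and Drosha-deleted replicate 3 their medians were 0.56, 0.81 and 0.63. The T and NK lymphoid genes lost it without control replicate 2 (adjusted p = 0.111), Drosha-deleted replicate 3 (adjusted p = 0.142) or Dicer-deleted replicate 2 (0.04, adjusted p = 0.128). Their median was 0.06 without Dicer-deleted replicate 1 and 0.17 without Drosha-deleted replicate 2. The contractile genes lost it without Drosha-deleted replicate 1 (0.07, adjusted p = 0.152), Drosha-deleted replicate 3 (adjusted p = 0.0542) or Dicer-deleted replicate 3 (0.05, adjusted p = 0.111).

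Targets of let-7, which loss of microRNAs would release, did not pass the test in any comparison with the scanner values. Their medians were 0.23 in Drosha-deleted and 0.20 in Dicer-deleted cells against controls (smallest adjusted p = 0.342), with the chromatin gene Hmga2 at 1.17 and 1.07. Stem and progenitor genes (smallest adjusted p = 0.346), mast cell and basophil genes (0.0634), erythroid genes (0.108), stromal and endothelial genes (0.283), p53 target genes (0.221), apoptosis regulators (0.468), genes of the microRNA machinery (0.468) and unfolded protein and amino acid stress genes (0.612) did not pass either, over the 3 comparisons.

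Among the 3 groups, 9 features differed in the moderated F test of the scanner values and 21 in that of the authors' values, with 1439 and 5066 at an unadjusted p under 0.05. The count with the scanner values was 3 without control replicate 3 and 2 whichever deletion array was left out. The authors' count was 6 without the column of control replicate 2. Simulated draws with no difference gave 29.5 features on average with the scanner values, more than the 9 found, and 6.07 with the authors' values. The differences of both deletions from the controls correlated across genes at 0.762 over 19857 genes measured on every array, where shared controls alone gave 0.876 in simulation (100 draws). In the authors' values the correlation was 0.828 against 0.665 simulated, and the covariance 0.159 against 0.0476. The scanner covariance was 0.189 against 0.295 simulated. The draws treated the control spread as independent between genes, but control replicate 2 was shifted over all genes in its scanner file. In the authors' values the deviations of control replicates 2 and 3 from the means over all columns correlated at 0.539. A difference of controls from deletions could add to that value, but control replicate 1 correlated with them at −0.286 and −0.213. The draws did not allow for control columns that move together. Neither source thus shows whether more than the shared controls give was present. Genes are not independent replicates, and with 3 controls they could not be divided between the comparisons.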

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

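The results of the next paragraph are differences between the effects of the Drosha and Dicer deletions that passed a direct test. Among the patterns weighed after it, Myl9, the interferon-stimulated genes and the monocyte genes did not pass such a test with the scanner values, and the megakaryocyte genes passed at the preset correlation alone. Of the tests in this part, those of loss of Drosha cleavage and of the slide for the primary microRNA transcripts, those of megakaryocyte RNA and of the slide for Myl9, and the scanner fits without control replicate 3 for the 3 lists were chosen after the results were seen.

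Between Drosha-deleted and Dicer-deleted cells, Cadm1 differed by −3.19 log2 units and the region between Jak1 and Ak4 on chromosome 4 (mm9, 101010948 to 101032148) by 2.95. Neither call held when a deletion array was left out, although both kept their direction. Cadm1 was not well above background in Drosha-deleted cells, so the exact size of its difference was not measured. Among lists that also held with an estimated correlation, the median difference was 1.5 for primary microRNA host transcripts, 1.60 for mRNAs reported as cleaved by Drosha, 0.252 for eosinophil genes (0.0676 without Dicer-deleted replicate 2) and 0.235 for B lymphoid genes (0.0676 without Drosha-deleted replicate 3 and 0.102 without Dicer-deleted replicate 2). The eosinophil and B lymphoid lists did not hold with an estimated correlation in the authors' values, and no explanation was tested for them or for Cadm1. The direction of the cleaved mRNAs is not independent evidence, since Myl9 was picked in published work probably done on these samples.

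Primary microRNA transcripts were higher in Drosha-deleted than in Dicer-deleted cells. Scaling or background that moves noncoding probes as a class is argued against by regions with no microRNA gene between their neighbours, whose median difference was 0.0434. That median does not test the background of the few host probes themselves. The size of the host list's difference did depend on the background method and the filter, and it stayed past the threshold with each. The 6 deletion arrays alone gave the host list an adjusted p of 5.95e-09 with an estimated correlation, but no control enters this difference and its median is fixed by construction, so this fit could not test slides or the control array, although all 6 arrays lay on a single slide. Loss of Drosha cleavage needs little change of the host list in Dicer-deleted cells against controls. Its median there was −0.0737, and −0.182 in the authors' values. It was −0.647 without control replicate 3 or with slide as a block, where control replicates 1 and 2 alone set the control level. With quantile normalisation, which also held control replicate 2, it was 0.349. The bounds written for the tests of slides and of loss of Drosha cleavage were set aside after their values were seen, and loss of Drosha cleavage stays open.

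Myl9 was 2.43 log2 units higher in Drosha-deleted than in Dicer-deleted cells (SE 0.37), short of the threshold over all genes. More megakaryocyte RNA in the Drosha-deleted cultures would lift other megakaryocyte genes alike, but the upper quartile of the 25 others was 0.557, with the abundant Ppbp at 5.44 ± 0.55 and 4.36 ± 0.17 (SD, n = 3). More stromal or smooth muscle RNA is argued against in the same way by an upper quartile of 0.239 over 32 other genes, with the smooth muscle gene Tagln lower in Drosha-deleted (1.68 ± 0.41) than in Dicer-deleted cells (2.36 ± 0.22; SD, n = 3). The fit of the 6 deletion arrays gave 2.43 by construction (SE 0.266), since no control enters this difference, so it could not test slides or the control array, although all 6 arrays lay on a single slide. A role of Drosha in cleaving the Myl9 mRNA stays open and was not tested.

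Interferon-stimulated and monocyte genes had lower medians in Drosha-deleted cells, and megakaryocyte genes in Dicer-deleted cells, than in controls, but none of these held with an estimated correlation (adjusted p = 0.932, 0.932 and 0.552 with the scanner values, 0.476, 0.476 and 0.267 in the authors'). A difference between slides as the whole cause would shrink the shifts once slide is taken out, but in the scanner values without control replicate 3, alone on its slide, they were −0.441, −0.428 and −0.534 against −0.354, −0.501 and −0.510 with it (adjusted p = 1.64e-06, 0.000232 and 0.00290; 0.940, 0.940 and 0.821 with an estimated correlation). In the authors' values they were −0.410, −0.478 and −0.701 with slide as a block (unblocked −0.333, −0.480 and −0.677; adjusted p = 0.215, 0.370 and 0.00258 with an estimated correlation). The bound set beforehand for excluding the slide, met by the megakaryocyte genes, assumed that the slide of each column is known, and the authors' column for control replicate 2 does not match its scanner file. The shifts thus stayed about as large, but each list missed the threshold with an estimated correlation in at least 1 of these fits. The interferon median was −0.204 without control replicate 1 (adjusted p = 0.0612). Slide, single arrays and an effect of the deletions thus stay open.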

How the results depend on the processing

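The authors' values and quantile normalisation without control replicate 2, and keeping the marked spots, were chosen after the data were seen; the cause was not tested for any change below unless stated. The direction of called genes was stable over 24 settings, the main fit among them, and 298 pairs of gene and comparison. Part of this stability is fixed by construction. A gene's difference cannot change with the robust prior, in a fit of the compared groups alone, or without an array of the group not compared. Slide as a block is the same fit as leaving out control replicate 3. In 6430 results the gene kept its side of the threshold, and 67 of these changed sign without a call in either fit. A further 148 became weaker, 215 became stronger, and 0 called ones reversed in limma. For lists, 1385 kept their side of the threshold, sign changes without a call included, 75 became weaker, 44 stronger and 5 reversed. A minimum 1.5-fold difference changed no count of genes in the 3 comparisons, and was not applied to the F test or the lists.

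Counts of genes past the threshold changed most. Against 7 for Drosha-deleted minus control, normexp background, quantile normalisation and no filter gave 0, the authors' values 39, slide as a block 13, the trended robust prior 18, array weights 29, the mean of probes 14 and marked spots kept 1, with 0 (without Drosha-deleted replicate 1) to 1369 (without control replicate 1) over arrays left out. Against 3 for Dicer-deleted minus control, normexp, quantile normalisation and no filter gave 0, and the stricter filter, the authors' values without control replicate 2, marked spots kept and a fit of the 2 groups 1 each, with 0 (without any single Dicer-deleted array) to 772 (without control replicate 1) over arrays left out. Against 2 between the deletions, normexp gave 1, quantile normalisation, no filter and marked spots kept 0, the authors' values 13 (11 without control replicate 2), the stricter filter 4, the trended robust prior 12, array weights 158, the mean of probes 7, quantile normalisation without control replicate 2 4 and the 2 groups alone 5, with 0 to 5 (without control replicate 2) over arrays left out. Against 9 in the F test, normexp, quantile normalisation and no filter gave 0, the authors' values 21, slide as a block 3, the prior 16, array weights 14 and marked spots kept 1, with 2 to 11 over arrays left out.

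Where limma called 0 genes, unadjusted p under 0.05 was reached by 1006 to 2355 genes for Drosha-deleted minus control, 711 to 1880 for Dicer-deleted minus control, 236 to 506 between the deletions and 1318 to 1391 in the F test. With replicate number as a block the counts were 19, 9, 12 and 19, although the numbers did not pair the samples. Array weights ran from 0.0341 for control replicate 2 to 4.48 for Drosha-deleted replicate 1; the REML method stopped with a convergence warning.

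Lists past the threshold numbered 5, 8 and 9 in the 3 comparisons and 2, 0 and 4 with an estimated correlation, which gives correlated members less weight. Correlation does not account for every loss. In Dicer-deleted minus control, B lymphoid and T and NK lymphoid genes lost their calls at estimated correlations of 0.016 and 0.024, near the preset 0.01. For Dicer-deleted minus control the authors' values, array weights, the authors' values without control replicate 2 and quantile normalisation without control replicate 2 each gave 5. Over arrays left out the ranges were 1 to 8, 3 to 9 and 7 to 11. The 5 reversals were B lymphoid genes in Dicer-deleted minus control without control replicate 2 (0.254) and with quantile normalisation without control replicate 2 (0.110), cell cycle genes there without control replicate 2 (0.0186), and, between the deletions, neutrophil genes without Dicer-deleted replicate 2 (−0.0625) and monocyte genes without Dicer-deleted replicate 3 (0.174). Over arrays left out these medians ran from −0.729 to 0.254 for B lymphoid genes, 0.0186 to 0.269 for cell cycle genes, −0.0625 to 0.807 for neutrophil genes and −0.357 to 0.174 for monocyte genes.

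For primary microRNA host transcripts the medians of 1.21 in Drosha-deleted cells against controls and 1.5 between the deletions fell to 0.683 and 0.854 in the authors' values, 0.570 and 0.744 with normexp background, and 0.475 and 0.391 with no filter, each past the threshold.

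The correlation of both deletions' differences, 0.769 over all genes tested, was 0.849 with quantile normalisation, 0.828 in the authors' values, 0.839 with slide as a block, 0.605 with array weights and 0.835 with marked spots kept, and 0.724 to 0.876 over arrays left out (SD 0.0531). Shifts of genes with microRNA seed matches were planned and not run. Genes whose group was not well above background, such as Olfr792 and Cadm1, have lower bounds in place of folds.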

Other observations

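The tests of regions near microRNA genes and the draws with no difference between groups were chosen after the result was seen; the counts of splits and the test of genes that hold a microRNA gene were planned before.

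Regions between the same neighbours as a microRNA gene may be parts of primary transcripts that Drosha cleaves, and genes that hold a microRNA gene may rise with them. Between Drosha-deleted and Dicer-deleted cells, 372 such regions had a median difference of 0.0988 (adjusted p = 0.00299; 0.962 with an estimated correlation), and 592 genes that hold a microRNA gene had one of −0.00388 (adjusted p = 0.834; 0.962 with an estimated correlation). Of the regions 14 were higher by more than 1 log2 unit, and of the genes 10. Of 2790 regions with no microRNA gene between their neighbours, 16 were. In the authors' values 12 of the 372 regions and 9 of the genes were, against 2 of the 2790. Neighbouring regions are not independent. The bound written for excluding each idea was an adjusted p of at least 0.05 with an estimated correlation; it was set aside after the values were seen, because a p that misses a threshold excludes nothing, and both ideas are left undecided. A rise of a few members, such as Aopep, would leave such medians near 0.

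Other splits of the same arrays were compared with the real groups. With 3 arrays against 3 there are 10 splits, so the share of splits is never under 0.1. For genes with the scanner values, the real count and the highest of the others were 7 and 1 for Drosha-deleted against control, 3 and 1 for Dicer-deleted against control, and 2 and 0 between the deletions, each reached by 1 of 10 splits, the real one. For lists the real count and the highest other were 5 and 10, 8 and 11, and 9 and 11, reached by 7, 6 and 7 of 10 splits. With the authors' values they were 39 and 187 for Drosha-deleted against control, reached by 2 of 10, then 4 and 1, and 13 and 0, reached by 1 of 10 each.

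The split with 187 genes set control replicate 1 and Drosha-deleted replicates 1 and 2 against control replicates 2 and 3 and Drosha-deleted replicate 3. A count several times the real one points to a structure of the samples. In the authors' values the columns of control replicates 2 and 3 correlated at 0.991, and their deviations from the means over all columns at 0.539, while those of control replicate 1 correlated with them at −0.286 and −0.213.

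For the F test, 100 splits of the 9 arrays were drawn. With the scanner values 1 split, the real one, gave as many as 9 genes and the highest other gave 7. Simulated draws with no difference between groups kept the spread of each group. As many as 9 genes came in 83 of 100, with a mean of 29.5. These draws treated the shift of control replicate 2 over all genes as independent noise in each gene. They cannot decide whether chance gave that count, and chance is not taken as excluded, whatever the splits gave. With the authors' values 4 splits, the real one included, gave as many as 21, too close to 5% for 100 draws to exclude chance, and 2 of 100 draws with no difference did. The highest other split gave 89, which again points to a structure of the samples.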
